A study of Mus musculus with 2 samples.

How the data were processed

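Ovaries were taken from mice at 2 days of age. Total RNA was isolated from the ovaries of single animals, and equal amounts from 8 animals were combined into 1 pool per genotype, per the labels' protocols. The control pool came from SmoM2 mice with 2 wild-type copies of Amhr2, and the mutant pool from SmoM2 mice with Cre at 1 copy of Amhr2. Biotin-labelled cRNA from each pool was hybridised to 1 Affymetrix mouse expression array with 45101 probe sets. Gene names came from the annotation of the array platform.

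The values are probe-set signal intensities on a linear scale, deposited by the authors as 1 column per array, and the submitters' processing notes name GCOS as the software. The values lie between 0.1 and 50465. The mean signal without the lowest and highest 2% of probe sets was 500.003 on both arrays, so both arrays share a common scale. The step that set it and the other software settings are not given in the sources used here, and detection calls were not used here. The signal intensities were used as deposited, with no background correction or second scaling in the main setting.

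The annotation listed 35890 probe sets. Of these, 34958 had 1 gene symbol and 932 had several. The other 9211 probe sets were not listed and are unnamed here, as are those with several symbols. The symbols were compared with a RefSeq gene table through the Entrez gene ID. There were 34754 matching probe sets, and 0 symbols differed. That table belongs to the GRCm38.p6 assembly. No build is named for the array annotation, so no coordinates are printed. The 64 control probe sets of the array were kept out of the gene counts.

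A probe set counted as measured when the higher of its 2 values reached 80.7, the median of all values of both arrays. The 27 control probe sets for Bacillus transcripts, which mouse RNA does not contain, had a median signal of 5.05 and a highest signal of 26.9. By this rule 23988 probe sets were measured. Of these, 20576 carried a single gene name, and they covered 12308 genes. Each gene was represented by its measured probe set with the highest mean signal, and the text gives other probe sets for some of the genes whose probe sets differed. The log2 ratio of mutant to control was taken after adding 22.2, the 25th percentile of all values, to both signals. It therefore understates the change of dim genes. Where 1 of the values lay under 80.7, the fold is given as a lower bound, the brighter signal divided by 80.7. That bound treats the signal minimum as the lowest measurable level. Counts of genes at a fold threshold use the log2 ratio, not this bound.

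With 1 array per group there is no replicate error, and no p-value was computed. Each array averages over 8 animals, but the spread between animals, litters and hybridisations was not measured. The spread that could be measured is that between probe sets of the same gene. Over 13386 measured probe sets of 5118 genes, its SD was 0.384 on the log2 ratio. When the probe sets were split by signal into 4 equal parts, the SD was 0.481 in the dimmest part and 0.305 in the brightest. This spread can also hold differences between transcripts of a gene. The number of arrays limits the precision of every value.

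Genes were counted at 2-fold or more in each direction. The 29 gene lists, the rule for named genes and 12 alternative settings were fixed before the data were examined. The lists covered the hedgehog pathway, the cell types of the ovary, steroid synthesis, neighbouring or admixed tissues, signalling pathways and reference genes. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists. The random lists had the same size and were drawn from genes in the same 1 of 20 bins of mean signal. A list was called shifted at or below percentile 2.5 or at or above percentile 97.5. These percentiles describe these 2 arrays and carry no replicate error. 22 lists had enough members, and about 1.1 of them would lie outside those limits if genes varied independently. Genes of the same cell type can vary together between pools, so the number to expect without a genotype effect was not measured.

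The rule for named genes takes the hedgehog target list and the genes that the alleles are named after (Smo and Amhr2). It also takes up to 4 measured members of each list with the largest absolute log2 ratio. By log2 ratio it adds the 15 highest and 15 lowest genes at 2-fold or more whose measured probe sets all had the same sign and whose symbols are not clone or model names. It also takes the sex-linked check genes. A gene outside the rule is marked as named after its values were seen, and the genes named from the added lists were all picked after their values were seen. A further 6 lists were chosen after the main values were seen and before their own were, apart from Mael, which the oocyte list also holds, and are reported among the additional observations. They hold growing oocyte, early germ cell, adrenal medulla, cholesterol synthesis, interferon response and protein folding stress genes.

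The counting and list steps were tested on simulated arrays drawn from the observed signals and the probe-set spread, with 12143 genes measured. Of genes simulated at 4-fold, 98.0% were called in each direction. Of genes simulated at 3-fold, 86.0% were called higher and 91.8% lower. Of 11930 unchanged genes, 126 were called at 2-fold. The spread had been measured on ratios that already held the added 22.2, and 22.2 was added again to the simulated signals. Calls among dim unchanged genes are therefore likely understated. Of 100 lists of random genes with no shift and independent noise, 5 fell outside the central 95%. A simulated list shifted by 0.6 lay at percentile 100. The 12 alternatives were changes of the array scaling, pseudocount, filter, probe-set choice and fold threshold. A further alternative, chosen after seeing the data, raised all values under 80.7 to that level with no pseudocount. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.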

Results

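The study asked how gene expression in the newborn ovary differs when hedgehog signalling is switched on in its somatic cells. The comparison used a conditional SmoM2 allele. SmoM2 is a constitutively active form of Smoothened, the membrane protein that passes on the hedgehog signal. Cre driven from the Amhr2 locus, which encodes the receptor for anti-Müllerian hormone, activates it in gonadal somatic cells. The control mice had no Cre and 2 wild-type copies of Amhr2. Cre and the changed Amhr2 copy therefore differ between the pools together with SmoM2 activation, and their effects cannot be told apart. The control group and the mutant group each held 1 array, hybridised with RNA pooled from 8 mice at 2 days of age. With 1 array per group no difference below has a replicate check, and fold values and percentiles describe these 2 arrays only. The share of probe sets at or above the signal minimum of 80.7 was 50.3% in the control pool and 49.8% in the mutant pool. Xist, the RNA of the inactive X chromosome, had signals of 19717 and 19080.5 in the control and mutant pools. The probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty read between 1.4 and 29.4, all under the signal minimum, and Ddx3y had no named probe set. The signal ratio between the 3' and 5' probe sets for beta-actin was 8.48 in the control and 10.5 in the mutant pool, and that for Gapdh was 3.28 and 4.98. The 18 probe sets for spiked hybridization controls had a median log2 ratio of 0.23 (range -0.01 to 0.39), and 17 of them were brighter on the mutant array.

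Hedgehog target genes were higher in the mutant pool. Hhip (Entrez gene 15245), a hedgehog-binding inhibitor that the pathway induces, had a signal of 1.1 in the control and 3215.5 in the mutant pool, at least 39.8-fold higher, and its other 3 probe sets read 324, 571 and 891 against 2.1, 3.3 and 4.3. Ptch1 (19206), the hedgehog receptor and a direct target, was 2.86-fold higher, at 15949 against 5574. Gli1 (14632), the transcription factor used as a pathway readout, was 264 against 103 (2.56-fold). Foxf1, a mesenchymal forkhead factor, was 695 against 62.0 (at least 8.61-fold). A second Foxf1 probe set stayed dim in both pools, at 14.9 and 22.9. Mycn was 1.78-fold and Rab34 1.58-fold higher. Ccnd1, Bcl2 and Ccnd2, with log2 ratios of 0.17, 0.15 and -0.54, did not reach 1.5-fold, and the 7 probe sets of Ccnd2 ranged down to -1.06. Of the 5 probe sets of Bcl2, 2 dim ones read 107 against 40.0 and 221 against 90.3. Of the 12 listed targets 9 were measured. Of these 6 were at least 1.5-fold higher and 0 were that much lower. Their median log2 ratio of 0.81 lay at percentile 100 of random lists, and was 0.83 with values under the signal minimum raised to it. Foxf2 and Foxl1 were too dim.

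The ligands, receptors and mediators of the pathway differed less and in both directions. The median log2 ratio of all 17 listed genes was 0.27 (percentile 99.2). Of these 5 were at least 1.5-fold higher and 1 was that much lower. Shh, the sonic hedgehog ligand, had a signal of 8.0 in the control and 602 in the mutant pool (at least 7.46-fold), although its other probe set read 4.6 and 0.7. The co-receptors Boc and Cdon were 2.16-fold and 2.01-fold higher, but a second probe set of Boc had a log2 ratio of only 0.27. Scube2, which helps release the ligand, was lower (427 in the control, 190 in the mutant, log2 ratio -1.08). Smo itself had log2 ratios of 0.28 and 0.49 on its measured probe sets, close to the probe-set SD of 0.38. Amhr2, the locus that carries Cre in the mutant, had a log2 ratio of -1.30 (8591 in the control, 3486 in the mutant). Its 3 probe sets gave -1.30, -1.26 and -0.26.

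**Figure D1:**
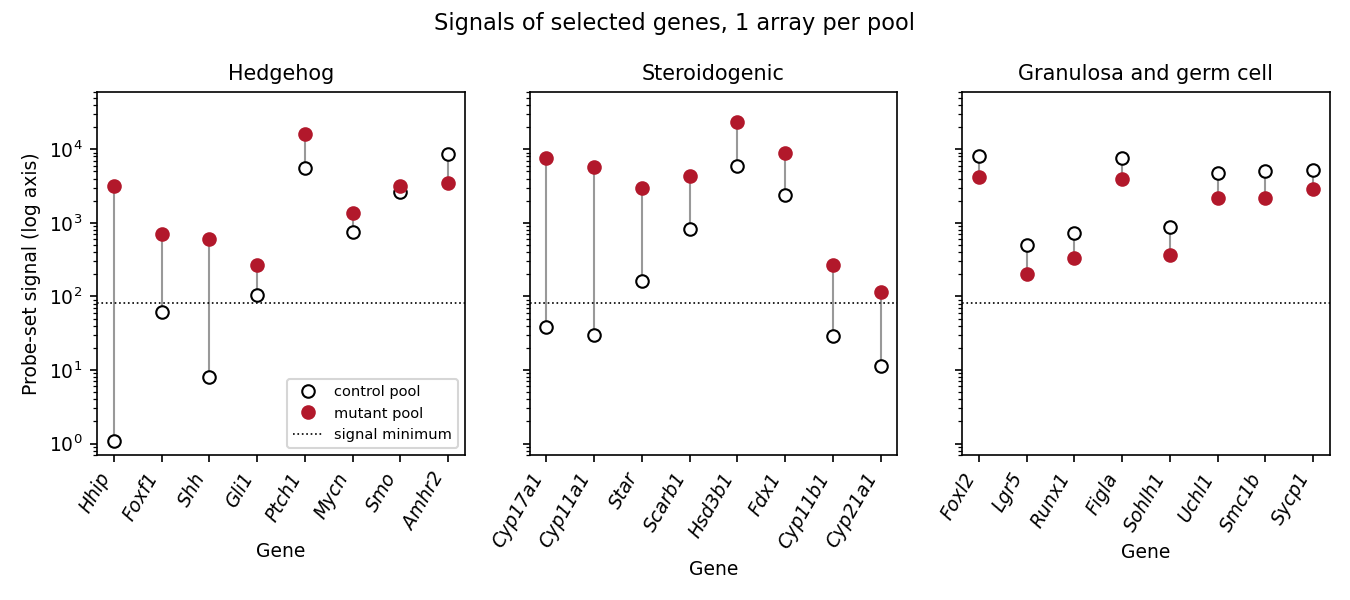
Probe-set signal (log axis) of selected hedgehog, steroidogenic, granulosa and germ cell genes in the control pool (open circles) and the mutant pool (filled circles), 1 array each, with the signal minimum of 80.7 dotted and with Hsd3b1 and Fdx1 chosen after their values were seen. Hhip, Cyp17a1 and Cyp11a1 lie under the minimum in the control and at 3215.5, 7532 and 5700 in the mutant pool, whereas Foxl2, Figla and Smc1b are lower in the mutant pool.

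Across all 12308 measured genes, 395 were at least 2-fold higher and 172 at least 2-fold lower in the mutant pool. In simulated arrays with the probe-set spread alone, 126 of 11930 unchanged genes reached 2-fold in either direction. A second measured probe set existed for 135 of the genes that were higher, and in 93 of them (68.9%) it was at least 1.5-fold higher too. Among the genes that were lower, 31 had a second probe set and 17 of these (54.8%) were at least 1.5-fold lower. Among the 4952 genes within 2-fold that had one, the second probe set passed 1.5-fold upward in 6.10% and downward in 11.7%. Of the genes lower 38.4% had a brighter signal under 2 times the signal minimum, and of the genes higher 23.0%. With both values required to reach the signal minimum 222 genes were higher and 84 lower, and with the pseudocount at the median of all values 247 and 48.

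The 15 highest genes by log2 ratio included Hhip, Cyp17a1 and Cyp11a1. Of the 15, 11 had control values under the signal minimum, so their order was not measured. Ibsp, a secreted bone matrix sialoprotein, was 1199 against 2.1 (at least 14.9-fold), while its other measured probe set read 118 and 25.5. Adh1, an alcohol and retinol dehydrogenase, was 58.6-fold higher (7587 against 129). Oxtr, the oxytocin receptor, was at least 9.07-fold higher, at 732 against 6.2, while a second probe set read 62.6 and 56.4. Vcam1, a cell adhesion molecule of stromal and endothelial cells, was at least 10.8-fold higher, Chil3 at least 8.59-fold, and Tenm2 at least 7.94-fold. The second measured probe sets of Vcam1 and Tenm2 read 119.8 against 18.1 and 148 against 28.3. Acsbg1, an acyl-CoA synthetase, and Mmd2 were 12.9-fold and 10.4-fold higher. Dleu7 and Sult1e1, the oestrogen sulfotransferase, were at least 2.45-fold and 2.36-fold higher. The remaining 2 of the 15 were Shh and Star. Of the 15 lowest genes, 14 had mutant values under the signal minimum and 13 had control values under 2 times the minimum. The exception with a strong signal was Rsad2, an interferon-induced antiviral protein, which was 1833 in the control and 428 in the mutant pool, and 216 and 77.3 on its second measured probe set. Chodl was at least 2.41-fold lower, at 194.5 in the control and 26.1 in the mutant pool. Zfp524, Irs2, Il10ra, Hnf4a, Nkx2-9, Tdrd1, Fn3k, Kcns3, Npff, Krt34, Fcgbp, Des and Dclk2 were the others, with control signals from 82.6 to 138.4.

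**Figure D2:**
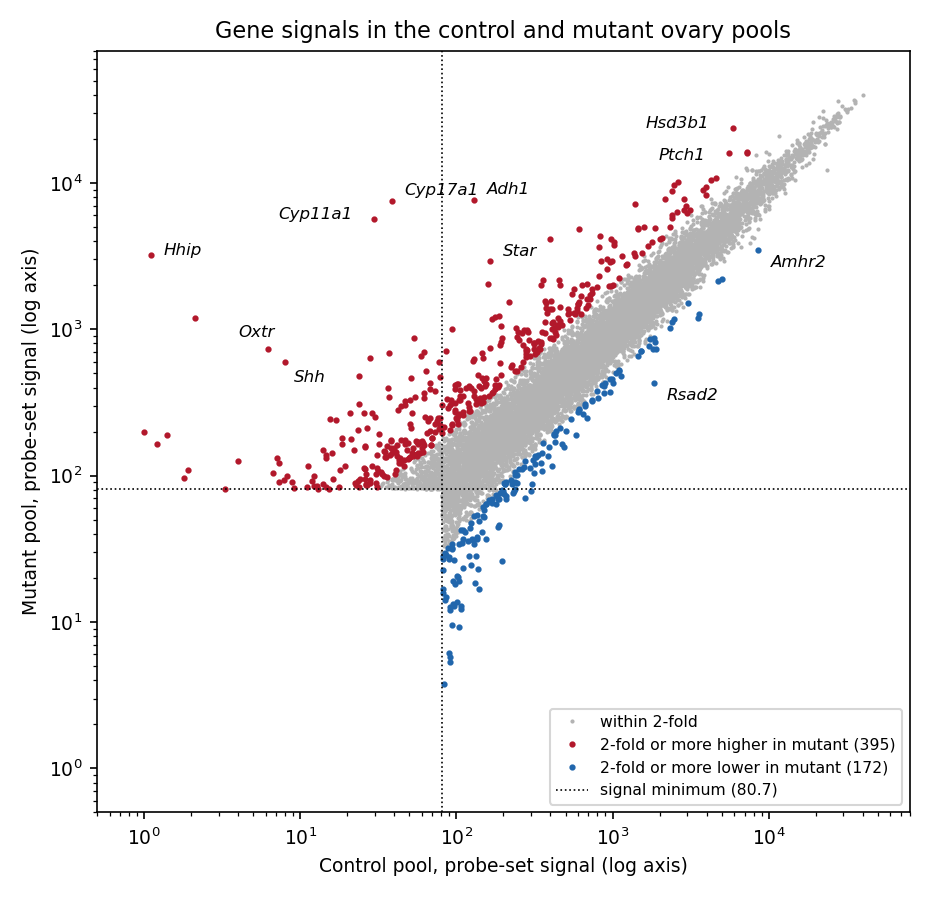
Signal of each measured gene in the mutant pool against the control pool (both axes log), with genes at 2-fold or more after adding 22.2 to both signals in red (395 higher) and blue (172 lower), and the signal minimum of 80.7 dotted. Of the 15 lowest genes 14 have mutant signals under the minimum, while Hhip, Cyp17a1, Cyp11a1 and Adh1 are above it in the mutant pool.

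Genes of steroid hormone synthesis showed the highest median of all lists. Cyp17a1 (13074), which makes androgen precursors, had a signal of 38.8 in the control and 7532 in the mutant pool (at least 93.3-fold). Cyp11a1 (13070), the enzyme that cleaves the cholesterol side chain, was 5700 against 29.6 (at least 70.6-fold), although a second measured probe set read 89.3 and 70.9. Star, which carries cholesterol into mitochondria, was 18.0-fold higher, and its other probe sets read 694 against 29.2 and 1000.2 against 65.4. Scarb1, the receptor for high-density lipoprotein, was 5.18-fold higher. Of 15 listed genes 9 were measured, 6 of them at least 2-fold higher and 0 lower by as much. The others at 2-fold, named after their values were seen, were Hsd3b1 (23765 against 5940) and Fdx1 (8821 against 2409). Nr5a1, Cyb5a and Inhbb, a gene that the granulosa list holds as well, also named after their values were seen, had log2 ratios of 0.53, -0.01 and -0.49. The median log2 ratio was 2.00 (percentile 100), and it was 2.00 as well with values under the signal minimum raised to it. Among the markers of the adrenal cortex, Cyp11b1 was at least 3.335-fold and Cyp21a1 at least 1.445-fold higher, Mc2r was 1.92-fold higher, and Nr0b1 had a log2 ratio of 0.03. A second Cyp21a1 probe set stayed under the minimum, at 38.5 in the control and 19.3 in the mutant pool. With 4 of 6 members measured, that list had no percentile.

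Germ cell genes were lower in the mutant pool. All 18 measured genes of the oocyte list of 20 had log2 ratios under 0, with a median of -0.57 (percentile 0). Of these, 8 were at least 1.5-fold lower and 2 at least 2-fold lower. The latter were Sohlh1, a germ cell transcription factor (877 in the control, 366 in the mutant), and Uchl1, a ubiquitin hydrolase (4716 and 2149). Figla, which drives zona pellucida genes, was 7591 and 3888, and Pou5f1 was 406 and 211. The meiotic prophase list, with 9 of 13 genes measured, had a median of -0.44 (percentile 0.36). Its 9 ratios were all under 0 and 4 genes were at least 1.5-fold lower. Smc1b, the meiotic cohesin subunit, had a log2 ratio of -1.17, Stag3 -0.89, the synaptonemal complex gene Sycp1 -0.815, and Tex11 -0.79.

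Genes of pregranulosa and granulosa cells were also lower as a list, with a median log2 ratio of -0.49 (percentile 0) over 15 measured of 19. Of these 7 were at least 1.5-fold lower and 2 at least 1.5-fold higher. Foxl2, the transcription factor that marks the granulosa lineage, was 8097 in the control and 4182 in the mutant pool (log2 ratio -0.95). Lgr5, a receptor of R-spondins, had a log2 ratio of -1.23 and Runx1 -1.10. Inhba, the activin subunit, was higher, at 164 against 47.0 (at least 2.03-fold). The Sertoli and testis list did not stand apart (median 0.13, percentile 80.2). Within it Cyp26b1, a retinoic acid hydroxylase, was 3.79-fold higher, at 332 against 87.5. Sox9 was 141 against 53.0 (at least 1.746-fold), Ptgds had a log2 ratio of -0.78 and Gata1 of 0.30.

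Stromal genes were higher in the mutant pool. The list of gonadal interstitial progenitor genes had a median log2 ratio of 0.70 (percentile 99.99), with 5 of 8 measured genes at least 1.5-fold higher and 0 lower by as much. Pdgfra, the receptor of platelet-derived growth factor, was 16038 against 7298 (2.20-fold), and its other probe sets read 499.5 against 223.5 and 87.7 against 29.1. Maf, Tcf21 and Nr2f1 were 2.04-fold, 1.87-fold and 1.73-fold higher, but a dim second probe set of Tcf21 had a log2 ratio of -0.11 and the 4 measured probe sets of Maf ranged from 0.135 to 1.02. For extracellular matrix genes the median was 0.61 (percentile 100), with 8 of 14 measured genes at least 1.5-fold higher and 0 lower by as much. Vcan, a large proteoglycan, was 2.42-fold, Eln, the gene of elastin, 2.33-fold, Col1a1 2.07-fold and Col5a2 1.78-fold higher. Leukocyte and macrophage markers had a median of 0.51 (percentile 99.8), with 4 of 8 at least 1.5-fold higher. C1qb was 2.37-fold, Ptprc 1.79-fold, the macrophage receptor Csf1r 1.71-fold and Lyz2 1.56-fold higher. Another probe set of C1qb had a log2 ratio of 0.24. The remaining measured markers, named after their values were seen, had log2 ratios of 0.40 (Tyrobp), 0.06 (Cd68), -0.004 (Adgre1) and -0.08 (C1qc).

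Smooth muscle and endothelial genes were higher as lists, with smaller medians. Smooth muscle contractile genes had a median log2 ratio of 0.43 (percentile 99.9), with 6 of 14 measured genes at least 1.5-fold higher and 2 lower by as much. Actg2 and Synpo2 were 3.44-fold and 3.18-fold higher and Tpm2 2.08-fold. The other probe sets of Synpo2 stayed under the signal minimum in both pools, with log2 ratios of -0.02, -0.57 and -0.17. Des, the gene of desmin, was 12.1 in the mutant and 91.4 in the control pool. It was counted as lower by its log2 ratio of -1.73, but the bound is only at least 1.133-fold. Its other probe set read 33.6 in the mutant and 29.3 in the control pool. Myocd, named after its values were seen, had a log2 ratio of -0.85. Without probe sets that can detect several transcripts the median was 0.03 (percentile 62.3), inside the random range. Endothelial markers had a median of 0.31 (percentile 99.4), with 3 of 16 at least 1.5-fold higher and 0 lower by as much. Sox18 had a log2 ratio of 0.84, Eng 0.60 and Cdh5 0.54, and Pecam1, counted by its log2 ratio of 0.61, was at least 1.446-fold higher. Without those probe sets the endothelial median was 0.23 (percentile 94.6), and with the signal minimum at the 75th percentile 0.42 (percentile 97.0), both inside the random range. Among angiogenic ligands and co-receptors, with a median of 0.30 (percentile 97.0, inside the random range but outside it under 5 of 10 alternatives), Angpt2, the antagonist ligand of the Tie2 receptor, was 4.22-fold, Nrp1 2.71-fold, Vegfc 1.89-fold and Angpt1 1.64-fold higher. The other measured probe sets of Vegfc had log2 ratios of 0.17 and 0.31. Pericyte markers did not stand apart (median 0.15, percentile 83.7), but did without the probe sets shared between transcripts (0.38, percentile 98.2). Pdgfrb was 1.80-fold and Notch3 1.59-fold higher, while Cspg4 had a log2 ratio of 0.515 and Anpep was at least 1.088-fold lower.

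**Figure D3:**
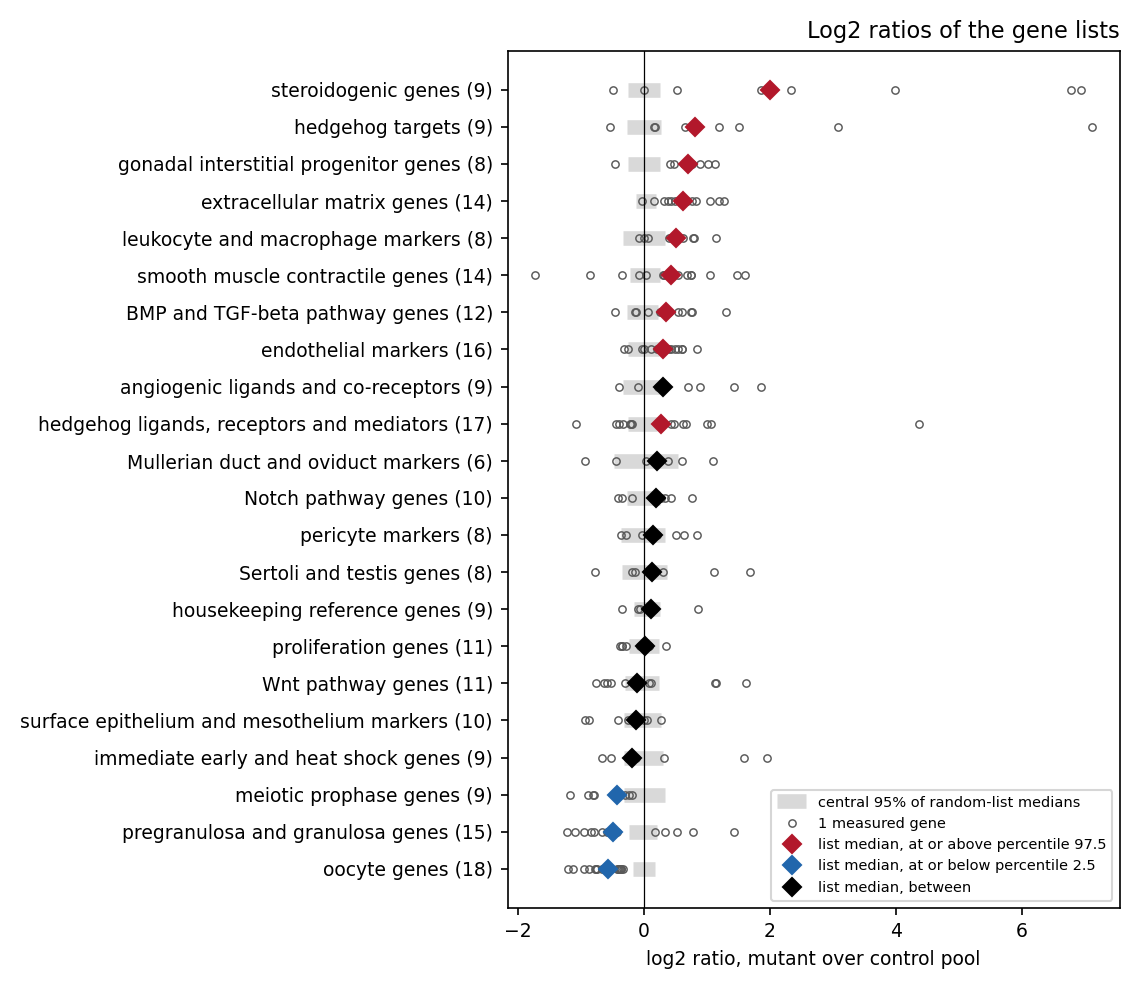
Log2 ratio of mutant over control for the measured genes of each list with at least 5 measured genes (open circles, number of genes in brackets), with the list median as a diamond and the central 95% of medians of 10000 matched random lists as a grey bar. Steroidogenic genes (median 2.00) and hedgehog targets (0.81) lie highest among these lists, and the oocyte, granulosa and meiotic lists lie below their random ranges.

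Among signalling lists, BMP and TGF-beta pathway genes had a median log2 ratio of 0.35 (percentile 99.8). With the signal minimum at the 75th percentile it was 0.25 (percentile 96.5), inside the random range. Bmp5 was 2.69-fold higher, Smad6 1.83-fold, Id2 1.70-fold and Id3 1.54-fold, but a second measured probe set of Id2 had a log2 ratio of only 0.18. The Wnt list had a median of -0.11 (percentile 33.3) over members that went both ways. Sfrp2 and Sfrp1, secreted Wnt antagonists, were 3.16-fold and 2.21-fold higher and Wnt5a was 2.27-fold higher, whereas Nkd1, an intracellular Wnt antagonist, had a log2 ratio of -0.77 with probe sets from -1.38 to 0.03. The Notch list (median 0.19, percentile 94.1) and the proliferation list (0.01, percentile 53.8) did not stand apart. Notch4 was at least 1.714-fold higher. Jag1, Hes1 and Jag2 had log2 ratios of 0.425, -0.41 and -0.35, and Cdk1, Bub1, Ccnb2 and Plk1 had -0.375, -0.36, -0.35 and 0.34. The list of immediate early and heat shock genes had a median of -0.19 (percentile 12.8). In it Hspa1b and Hspa1a, near-identical heat shock genes that such probe sets cannot fully tell apart, were 3.90-fold and 3.10-fold higher, and Fosb and Atf3 were at least 1.107-fold and 1.52-fold lower. The housekeeping list had a median of 0.10 (percentile 78.3), with 0.16 for Hprt. The 2 measured probe sets of B2m had 0.86 and 0.13, those of Actb -0.35 and 0.36, and the 3 of Pgk1 lay between -0.23 and 0.145.

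Few markers of other tissues were measured, with 1 of 9 for adipocytes, 2 of 8 for kidney, 1 of 8 for skeletal muscle and 2 of 8 for nerve and glia, the others being too dim or without a named probe set. Surface epithelium and mesothelium markers did not stand apart (median -0.14, percentile 24.4), with log2 ratios of -0.94 for Krt18, -0.88 for Krt8, -0.41 for Krt19 and 0.26 for Msln. Müllerian duct and oviduct markers had a median of 0.20 (percentile 78.3) over 6 genes. Hoxa9 was 2.22-fold higher on 1 probe set and had a log2 ratio of 0.23 on the other, Hoxd10 had 0.61, and Emx2 -0.45 on the log2 scale. Ovgp1 was 83.7 in the control and 33.3 in the mutant pool (at least 1.037-fold lower). Erythroid genes had only 4 measured members and no percentile. Alas2, the haem synthesis enzyme of red cells, was 409 in the control and 116 in the mutant pool (log2 ratio -1.64), Slc4a1, the red cell anion exchanger, had -1.16, Epb42 -0.52 and Klf1 -0.18. In the nerve and glia list, S100b was at least 2.005-fold higher and Th had a log2 ratio of -0.265. Kap and Umod of the kidney list had 0.64 and -0.175, Mylpf was the 1 measured skeletal muscle gene (-0.43), and Car3 the 1 measured adipocyte gene (-0.80).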

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

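Probe sets without a single gene name lay outside the gene comparisons, and many of them differed between the pools. Of 3381 such measured probe sets, 101 were at least 2-fold higher and 129 at least 2-fold lower in the mutant pool. Among the 12308 named genes 395 were higher and 172 lower. The named genes are each counted by their brightest probe set, so the counts are in unlike units. Their genes were not analysed here, and no biological or technical explanation was tested for them.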

How the results depend on the processing

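The alternative that raises values under the signal minimum to it was chosen after the data were seen, and the others before. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out and no other split of the samples was possible. The count of genes higher (395) was 247 with the pseudocount at the median, 678 with no filter on dim probe sets, 222 with both values at or above the minimum, 182 with a minimum at the 75th percentile, 1147 at 1.5-fold and 155 at 3-fold. The count of genes lower (172) was 291 with a pseudocount of 0, and under those same 6 settings 48, 441, 84, 48, 972 and 26. Under the other alternatives both counts stayed within 1.5 times, at 342 to 524 higher and 125 to 170 lower. With values raised to the minimum, 304 of the 395 and 106 of the 172 genes remained.

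Of 12 lists outside the random range, 9 stayed outside under every alternative run, and 226 of 236 combinations of list and alternative kept their call. Without probe sets shared between transcripts, the smooth muscle median was 0.0322 and the endothelial median 0.2349, both inside the range, and the pericyte median of 0.3768 was now outside. With the minimum at the 75th percentile, the endothelial (0.4250) and BMP and TGF-beta (0.2533) medians lay inside. The angiogenic median was outside under quantile scaling (0.3279), no filter (0.6908), both values at or above the minimum (0.4932), the mean of probe sets (0.2957) and values raised to the minimum (0.3336). The cause was not tested for these lists. The steroidogenic median ranged from 1.86 to 2.03 and the hedgehog target median from 0.65 to 0.86. Of 69 named genes at 2-fold or more, 40 kept it under every alternative that kept the gene, and 0 of 134 reversed. Scaling moved the median of all genes by at most 0.0373 on the log2 scale. Of the genes called lower 38.4% had a brighter signal under 2 times the minimum, and of those called higher 23.0%.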

Other observations

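Genes of cholesterol synthesis were higher in the mutant pool. The genes named here from this and the other added lists were picked after their values were seen. Of 15 measured genes, 8 were at least 1.5-fold higher, 0 were lower by as much, and the median log2 ratio was 0.63. Cyp51 and Msmo1, which act on sterol intermediates, were 3.37-fold and 3.34-fold higher. Idi1 was 2.80-fold, Lss, the lanosterol synthase, 2.51-fold and Dhcr7 2.10-fold higher, while Fdft1 and Sc5d had log2 ratios of -0.25 and -0.33. The hypothesis that these genes are higher along with the steroidogenic genes was tested on a list chosen before its values were seen, and its median lay at percentile 100 of random lists. Which cells carry these transcripts, and whether more cholesterol is made, was not measured. That steroid-producing cells make more of it is a hypothesis only, and these 2 arrays cannot separate it from a difference between the pooled animals.

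Germ cell genes differed in how much lower they were. Genes of growing oocytes had a median log2 ratio of -0.37 over 18 genes (percentile 0.02), with -0.16 for Nlrp14, -0.41 for Padi6 and -0.81 for Tcl1. The added list of early germ cell and meiotic genes had a median of -0.75 over 19 genes (percentile 0). The meiotic prophase list, fixed beforehand, had a median of -0.44 over 9 genes, closer to that of the growing oocyte genes. Among them Syce1, of the synaptonemal complex, had -1.21, and the piRNA pathway genes Mov10l1, Asz1 and Tdrd9 had -1.19, -1.11 and -1.08, whereas Ythdc2 had 0.08. These lists were prompted by the spread within the oocyte list and chosen before their own values were seen, apart from Mael in the early list, which the oocyte list also holds.

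Rsad2 and the Hspa1 genes did not stand for wider groups. The hypothesis that interferon response genes are lower with Rsad2 was not borne out, since 7 measured genes had a median log2 ratio of 0.33 (percentile 92.81). Cmpk2, an interferon-induced kinase, was 3.10-fold higher and Irf7 at least 1.24-fold lower. The hypothesis that protein folding stress genes are higher with Hspa1a and Hspa1b was not borne out either, with a median of 0.06 over 12 genes (percentile 67.44) and 0.34 for Dnajb1.

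Among the tests below, those on adrenal cortex cells and on a lower share of oocyte RNA as sources of the steroidogenic pattern, and the test of the gap between stromal and germ cell or granulosa lists, were chosen after the result was seen. Steroidogenic genes were higher in the mutant pool, and the scaling of the arrays was not the cause, since the lowest list median under 3 scalings was 1.9576. A lower share of oocyte RNA would raise other somatic lists alike, but the steroidogenic median lay 1.2989 above the highest of 4 other somatic list medians. Adrenal tissue with medulla stays open, because the adrenal medulla list had a median of 0.33393 (percentile 90.4) with members both ways, such as Slc18a2 (3629 in the control, 1949 in the mutant) and Ddc (119 and 258). Of its 9 measured members 6 had log2 ratios above 0, but some of these stayed close to the signal minimum in the mutant pool. Among them Dbh read 90.0, Pnmt 103 and Chga 108 there. Th, held by the nerve and glia list, had a log2 ratio of -0.265. Adrenal cortex cells stay open. All 4 measured members of the adrenal cortex list had log2 ratios above 0, but of unlike size. Cyp11b1 was at least 3.335-fold and Mc2r 1.92-fold higher, Nr0b1 had a log2 ratio of 0.03, and Cyp11b2 and Akr1b7 were not measured. The lower log2 ratio of Cyp21a1 and Cyp11b1, 2.0551, decides nothing, since it is set against control values under the signal minimum, allows Cyp21a1 to be as little as 1.445-fold higher, and a second Cyp21a1 probe set read 38.5 in the control and 19.3 in the mutant pool. The hedgehog over-activation named by the design could account for the pattern and is untested beyond this pair of pools. It cannot be told apart from Cre itself or from the Cre insertion at 1 copy of Amhr2, since the control mice had neither.

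Oocyte and granulosa genes were lower and stromal genes higher in the mutant pool. The oocyte, granulosa, interstitial progenitor and matrix lists lay outside the random range in 12 of 12 combinations with 3 scalings, which decides nothing, because the random lists are rescaled with them. The smallest gap between a stromal median and the oocyte or granulosa median was 1.0999. Between the ranges of signal-matched random lists it was at most 0.4954. One factor per array would move both groups of lists alike, so it alone would not part them. On a trend with signal the gap decides nothing further. Each list already lay beyond its own random range, in opposite directions, so every gap had to exceed that limit. One factor for all germ cell genes, such as fewer oocytes per unit of RNA, is not settled here. Growing oocyte genes lay 0.39363 above the 18 early germ cell genes other than Mael (median -0.76), against -0.29 to 0.30 in random reassignments. That gap argues against one equal factor for the genes of these lists only. Both lists were prompted by the spread within the oocyte list of these same arrays. The meiotic prophase list, fixed beforehand, had a median of -0.44, near the growing oocyte median of -0.37. A lower share of oocytes stays open, alone or with a difference in their stage. A difference in litter or dissection between the pools and the genotype stay open too.

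More genes were higher than lower at 2-fold. At 1.5-fold the counts were closer in proportion, at 1147 higher and 972 lower. Probe sets without a single gene name, counted per probe set and not per gene, went the other way at 2-fold, with 101 higher and 129 lower. Signal-dependent scaling and noise of dim probe sets are both argued against as the whole cause, since the ratio of genes higher to lower was 3.792 after loess and 2.4392 with values under the minimum raised to it. The hybridization and the RNA quality of each pool cannot be separated from the genotype, and the spiked controls were themselves brighter on the mutant array (median log2 ratio 0.23). The ratio of 3' to 5' signal for Gapdh was also higher there (4.98 against 3.28). A biological difference may contribute, as a hypothesis only.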
